A study of Mus musculus with 16 samples.

How the data were processed

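The series holds mouse kidney RNA of 16 labelled biological replicates, measured on single-colour whole-transcript arrays, 1 array per replicate. Per the labels, frozen kidney tissue was homogenised, total RNA was isolated with RNA-Bee and checked on a Bioanalyzer, and random-primed cDNA from the Ambion WT kit was labelled with biotin. The deposited table gives log2 probe set levels, with values from 3.34 to 14.71. Partek version 6.4 and RMA, a background correction and summary method for arrays, are named in the submitters' processing notes. Their order, their settings and the genome build are not given in the sources used here. No raw image files were used here.

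The table has 35556 rows. The probe table pairs 21789 of them with exactly 1 gene symbol, 1621 with several symbols and 12146 with none. Rows with 1 symbol were tested, and where a gene had several such rows (999 genes) the row with the highest mean over the 16 arrays stood for it, which left 19938 genes. Of the rows with 1 symbol, 21698 had an Entrez identifier in the reference gene table (assembly GRCm38.p6, used for names and chromosomes only), and that table changed 0 symbols. No pair of arrays held identical values (0 pairs). Array medians lay between 5.92 and 6.03 and were not adjusted further. For arrays the number of animals limits the precision, and no counting interval applies.

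Groups came from the sample titles. The tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. The 4 groups were fitted together in limma 3.58.1 under R 4.3.3, as a model with 1 mean per group (12 residual degrees of freedom, 2.83 prior degrees of freedom). Each comparison was 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were VHL-KO against control, AKI against control, VHL-KO/AKI against AKI, VHL-KO/AKI against VHL-KO, and the interaction, which is the knockout difference in injured kidneys minus that in uninjured kidneys. In the group values, the error is the SD over arrays. In the differences it is the standard error of the limma fit.

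Named genes are Vhl first. Next come the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap in any array, without predicted or numbered names (4 and 4, called genes only, for the interaction). Last, from each list, come up to 4 called members with the largest change, or the pair with the smallest p where no member was called. A pair of genes outside this rule (Vmn1r32 and Vmn1r38) is also given and said to be so.

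The 36 gene lists held 425 members, of which 388 matched a tested gene by symbol or older symbol. They cover HIF target genes, glycolysis and lactate, fatty acid oxidation, the citric acid cycle, oxidative phosphorylation, gluconeogenesis, tubular injury markers, the haem and oxidative stress response, immediate early genes, heat shock and endoplasmic reticulum stress, cytokines and chemokines, acute phase and complement, the interferon response, p53 target genes, proliferation, cholesterol synthesis, autophagy and mitophagy, the circadian clock, the osmotic response and fibrosis and matrix. Cell type and tissue lists cover the proximal tubule, thick ascending limb, distal convoluted tubule, collecting duct, podocyte, endothelium, fibroblast and smooth muscle, macrophage, neutrophil, lymphocyte, erythrocyte, adipose tissue and adrenal gland. Sex chromosome genes, male-biased kidney genes and female-biased kidney genes complete them. Each list was tested with camera from limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation, which allows for genes of a list varying together, and fry, a rotation test of direction, were run beside it. A pair of further lists (erythroid precursor, platelet and megakaryocyte) was written after the first results and is used in the last part only.

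The test was checked on simulated data with the real group sizes and 200 changed genes among 19938. For VHL-KO against control it recovered 92% of 2-fold and 100% of 4-fold changes with 7 false calls. For AKI against control the values were 96%, 100% and 11. For VHL-KO/AKI against AKI they were 97%, 100% and 10. For VHL-KO/AKI against VHL-KO they were 96%, 99% and 11. For the interaction they were 74%, 98% and 8. Over 20 simulations without change, 36 lists each, camera at the preset correlation called 5 lists, and a list given a shift was recovered. The simulated genes varied independently, so these counts do not give the false calls to be had where genes of a list vary together.

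Alternatives replaced 1 choice at a time: the rows tested, a filter on dim genes (13292 genes left), centring, quantile or cyclic loess scaling of the deposited values, trend and robust variance, array weights, a fit of the compared groups alone, the replicate number as a block, the sex-linked level (Xist minus the mean of the Y-linked genes) as a covariate, a fold of at least 1.5, an adjusted p under 0.01, and leaving out each array in turn. Leaving out 2 arrays together (control 3 and AKI 4) was added after the data had been seen. Equal replicate numbers did not mark related animals. After subtraction of group means, 3 of 20 pairs of arrays with equal numbers had a correlation over 0.1, with a range from -0.381 to 0.204. The block was therefore used as an alternative only.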

Results

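Mouse kidney RNA was profiled on 16 single-colour whole-transcript arrays, 1 per labelled replicate. The series asks how loss of Vhl in the renal tubule changes kidney transcripts with and without acute kidney injury, with HIF and metabolism named in its title. Vhl encodes the von Hippel-Lindau protein, which marks the hypoxia-inducible factors (HIF) for breakdown. The design text places every mouse in a transgenic line in which doxycycline switches on deletion of Vhl in tubule cells, whereas the genotype label reads wild type for the mice not given doxycycline. Control mice (n = 3) were untreated. VHL-KO mice (n = 3) received doxycycline, 0.1 mg per 10 g, 4 days before they were killed. AKI mice (n = 5) received 50% glycerol into a hind limb muscle, 0.05 ml per 10 g, which causes muscle breakdown and acute kidney injury. Their drinking water was withdrawn from 20 h before to 24 h after the injection. VHL-KO/AKI mice (n = 5) received both. No group received doxycycline without the knockout, or water withdrawal without glycerol. The labels say that both sexes were used and give no sex per animal. Array medians lay between 5.92 and 6.03 on the log2 scale. The number of animals limits the precision of every value.

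The largest difference among the arrays lay between injured and uninjured kidneys, which also differed in sex-linked signal (below). The first principal component held 57.1% of the variance and placed the 6 uninjured arrays between -41.9 and -33.9, VHL-KO/AKI arrays between -1 and 32.1, and the AKI arrays other than AKI 4 between 36.5 and 42.8. AKI 4 lay at 5.8. Its mean correlation with its own group was 0.973, against 0.988 to 0.989 for the other AKI arrays.

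Sex-linked transcripts divided the arrays in the same place as injury. Xist, which is transcribed from the inactive X chromosome of female cells, lay between 10.23 and 11.47 in the 6 uninjured arrays and between 4.16 and 5.08 in the 10 injured arrays. The mean of the Y-linked genes Uty, Eif2s3y and Kdm5d lay between 7.77 and 8.26 in the injured arrays. It lay between 4.81 and 5.01 in controls 1 and 2 and the VHL-KO arrays. Control 3 held both, with Xist at 10.23 and the Y-linked mean at 7.43. Whether this array holds RNA of a single animal or a mixture of both sexes is not known here, so n = 3 for controls rests on the labels. Every comparison of injured with uninjured kidneys therefore also compared arrays of opposite sex-linked signal, whereas AKI and VHL-KO/AKI did not differ in Xist (-0.10, 95% interval -0.47 to 0.26).

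**Figure D1:**
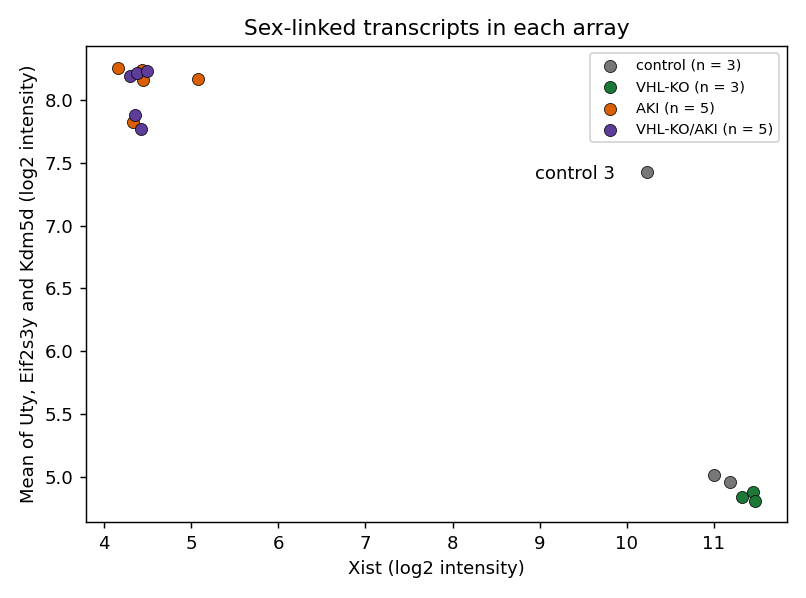
Xist against the mean of 3 Y-linked genes, both in log2 intensity, with 1 dot per array and a colour per group. The 6 uninjured arrays lie at Xist levels of 10.23 or more and the 10 injured arrays at 5.08 or less. Control 3 is the array with both signals.

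Vhl, the targeted gene, was lower in every array of the knockout groups than in any other array. Its level was 7.06 ± 0.04 in controls (SD, n = 3), 6.65 ± 0.04 in VHL-KO (n = 3), 7.16 ± 0.12 in AKI (n = 5) and 6.50 ± 0.12 in VHL-KO/AKI (n = 5). In injured kidneys Vhl fell by 0.67 on the log2 scale (SE 0.0674, limma adjusted p = 9.98e-05). In uninjured kidneys the difference was -0.40 (SE 0.087) and did not pass (adjusted p = 0.0565). Injury itself went with differences of 0.11 (adjusted p = 0.348) without and -0.15 (adjusted p = 0.217) with the knockout, and the interaction was -0.26 (adjusted p = 0.369). The position of the probes relative to the deleted part of the gene is not known here, and cells outside the tubule keep the gene.

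VHL-KO against control asked what the deletion changes in the uninjured kidney. Genes for the use of glucose and the response to low oxygen rose together. Pfkl, the liver form of the glycolytic enzyme phosphofructokinase, rose from 8.29 ± 0.40 to 10.31 ± 0.12 (SD, n = 3 and 3), a log2 change of 2.02 (SE 0.219, adjusted p = 0.000464). Pdk1, a kinase that restrains the entry of pyruvate into the citric acid cycle, rose by 1.57 (SE 0.211, adjusted p = 0.00277). Adm, which encodes the vasodilator adrenomedullin, rose 4.95-fold (log2 change 2.31, SE 0.233, adjusted p = 0.00031). Egln3, a prolyl hydroxylase that acts on HIF, rose from 8.33 ± 0.40 to 10.45 ± 0.52 (adjusted p = 0.0139). Each of these genes was higher in all 3 knockout arrays than in all 3 controls.

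Of 26 measured HIF target genes, 7 rose, 0 fell and 19 did not pass, and 11 rose when adjusted over the list alone. They included P4ha1, which modifies collagen (log2 change 1.38), and the mitophagy gene Bnip3 (1.26). The list median was 0.49 (camera adjusted p = 1.28e-16, and adjusted p = 0.017 with an estimated correlation). Of 19 glycolysis and lactate genes 7 rose, 0 fell and 12 did not pass, and 13 rose when adjusted over the list alone. Slc16a3, which exports lactate, rose by 1.63 and Pfkp by 1.42. The list median was 0.68 (camera adjusted p = 4.07e-17, and adjusted p = 0.0185 with an estimated correlation). In the list of autophagy and mitophagy genes, Bnip3l rose by 0.53 and the other 10 of 11 did not pass (camera adjusted p = 0.111).

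Markers of other cells also stood higher in VHL-KO. None of 8 endothelial genes passed over all genes (0 of 8), and 7 of the 8 rose when adjusted over the list alone. Tie1, an endothelial receptor, differed by 0.64 (adjusted p = 0.0721) and Emcn by 0.48 (adjusted p = 0.0674). As a list, the endothelial genes were higher, with a median of 0.58 (camera adjusted p = 4.99e-10, and adjusted p = 0.0125 with an estimated correlation). The 13 proliferation genes were higher as a list, with a median of 0.34 (camera adjusted p = 6.34e-07, and adjusted p = 0.0431 with an estimated correlation). Of these 0 passed over all genes and 7 rose when adjusted over the list alone. Mki67 differed by 0.71 (adjusted p = 0.124) and Ccna2 by 1.05 (adjusted p = 0.0907). The erythrocyte list, of which 2 of 6 members were measured, was higher (camera adjusted p = 2.06e-05, and adjusted p = 0.017 with an estimated correlation). Its member Alas2, the first enzyme of haem synthesis in red cell precursors, rose by 2.11 (SE 0.266, adjusted p = 0.00176).

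Single genes outside these groups rose as well. Vmn1r32, a vomeronasal receptor gene that the naming rule leaves out and that was chosen after its values were seen, had the largest rise of the called genes, by 6.14 (SE 0.279, adjusted p = 1.92e-08). Hmox1, which degrades haem, rose by 2.11 (adjusted p = 0.0148) and was the only 1 of 18 genes of the haem and oxidative stress list to pass. That list was not called (median 0.01, mean 0.14, camera direction down, adjusted p = 0.779). Myc rose by 1.58 (adjusted p = 0.00467) as the only 1 of 17 tubular injury markers, and the matrix gene Ccn2 by 0.98 (adjusted p = 0.0329) as the only 1 of 10 fibrosis genes. Edn3, a vasoactive peptide of the endothelin family, rose by 2.03, the platelet chemokine Ppbp by 2.22 and the defensin Defb19 by 3.06. Of the 105 called genes 10 fell. Dnase1, a secreted nuclease, fell by 1.36 (SE 0.211, adjusted p = 0.00791). The organic anion exporter Abcc2 fell by 0.85 (adjusted p = 0.024), and Ethe1, which oxidises sulphide in mitochondria, by 0.68 (adjusted p = 0.0393). Cyp4f14 fell by 0.68, Klk1b22 by 0.66, Plekha6 by 0.64, Dusp9 by 0.54 and Gng12 by 0.44.

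Genes of mitochondrial fuel use did not pass. The genes that passed were 0 of 21 of fatty acid oxidation (median 0.15), 0 of 19 of the citric acid cycle (median 0.02, camera direction down, adjusted p = 0.407), 0 of 21 of oxidative phosphorylation (median -0.07) and 0 of 6 of gluconeogenesis (median 0.10). Oxidative phosphorylation was called lower as a list by camera (adjusted p = 0.039), with adjusted p = 0.866 with an estimated correlation. The call ended after centring (adjusted p = 0.135) and without control 1, VHL-KO 1 or VHL-KO 2. Genes of proximal tubule transport and metabolism were lower as a list (median -0.38, camera adjusted p = 4.08e-06), with adjusted p = 0.587 with an estimated correlation. Of its 16 members 0 passed over all genes and 1 fell when adjusted over the list alone. Male-biased kidney genes were lower too (median -2.15, camera adjusted p = 3.87e-06), with adjusted p = 0.362 with an estimated correlation. That call ended without control 3 (adjusted p = 0.0913), the array with Y-linked signal.

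In all, limma called 95 genes higher and 10 lower of 19938 (1664 at an unadjusted p under 0.05), 38 and 1 of them by at least 2-fold. Each of the 105 separated all arrays of its 2 groups, as did 17.2% of all genes, against 10% by chance for 3 against 3. After each array was centred on its median, 47 were higher and 13 lower. The count was 55, 48 and 34 without controls 1, 2 and 3, 41 without VHL-KO 1, 35 without VHL-KO 3 and 235 without AKI 4, which enters through the shared spread. With the sex-linked level as a covariate, which differs here through control 3, limma called 18 genes, all among the 105 (1196 at an unadjusted p under 0.05), with the median standard error up from 0.113 to 0.137. Of 24 named calls, 8 (Adm, Alas2, Edn3, Pfkl, Pdk1, P4ha1, Myc and Klk1b22) held with any array left out. The losses were 11, 12 and 14 calls without controls 1, 2 and 3, and 14, 4 and 15 without VHL-KO 1, 2 and 3. Bnip3 and Bnip3l were lost after centring, Abcc2 after quantile scaling, Cyp4f14 and Dusp9 after cyclic loess, and Defb19 and Ccn2 under all 3 scalings.

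**Figure D2:**
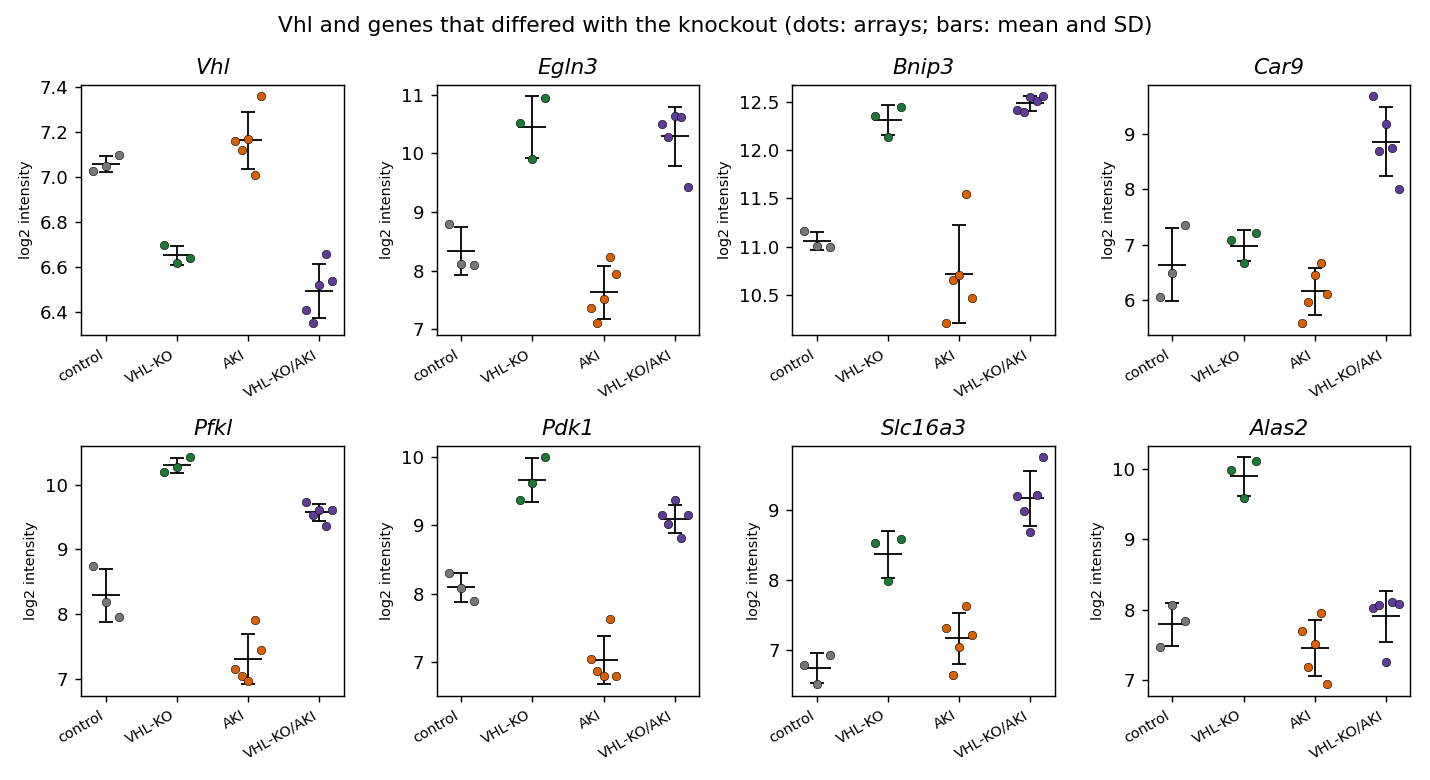
Log2 intensity of Vhl and 7 genes that differed with the knockout, by group, with 1 dot per array and bars for the mean and SD (n = 3, 3, 5 and 5). Every knockout array lies below the others for Vhl. Car9 is at 6.98 ± 0.28 in VHL-KO and 8.86 ± 0.62 in VHL-KO/AKI.

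AKI against control asked what the glycerol injury changes, together with water withdrawal and, in these animals, an opposite sex-linked signal. Markers of damaged tubule cells rose by the largest amounts. Havcr1, which encodes kidney injury molecule 1, rose from 6.38 ± 0.32 (SD, n = 3) to 12.14 ± 1.63 (n = 5), a log2 change of 5.75 (SE 0.646, adjusted p = 2.87e-05). Krt20, an epithelial keratin, rose by 6.44 (SE 0.538, adjusted p = 3.49e-06) and Lcn2, which binds bacterial iron carriers, by 5.13 (SE 0.238, adjusted p = 1.37e-08). Of 17 tubular injury markers 15 rose, 0 fell and 2 did not pass, and 15 rose when adjusted over the list alone (median 1.60, camera adjusted p = 3.04e-12, and adjusted p = 0.115 with an estimated correlation). Xist fell by 6.32 in the same arrays. The injury list of AKI 4 lay 0.637 below the mean of the other AKI arrays.

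Genes of the haem and oxidative stress response rose with the injury markers. Of 18 measured, 13 rose, 1 fell and 4 did not pass, and 14 rose and 1 fell when adjusted over the list alone (median 0.97, camera adjusted p = 1.47e-08, and adjusted p = 0.106 with an estimated correlation). Hmox1 rose from 7.56 ± 0.25 to 12.17 ± 0.45 (log2 change 4.61, SE 0.32, adjusted p = 1.01e-06). The cystine transporter Slc7a11 rose by 4.21, Srxn1 by 3.03 and the biliverdin reductase Blvrb by 2.08. Immediate early genes rose in 11 of 12 cases and in 12 when adjusted over the list alone (median 1.53, camera adjusted p = 2.78e-08, and adjusted p = 0.18 with an estimated correlation). Atf3 rose by 3.93, Egr1 by 2.96, Klf6 by 2.40 and Jun by 2.38. Of 12 genes of heat shock and endoplasmic reticulum stress 11 rose, also when adjusted over the list alone (median 1.18, camera adjusted p = 1.87e-07, and adjusted p = 0.0941 with an estimated correlation). Hspb1 rose by 3.15, Hspa1a by 2.50, Chac1 by 2.30 and Asns by 1.91.

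Inflammatory genes and markers of other cells moved as well. Of 16 cytokines and chemokines 8 rose, also when adjusted over the list alone (median 0.48, camera adjusted p = 0.000156, and adjusted p = 0.106 with an estimated correlation). Socs3, which restrains cytokine signals, rose by 2.01, Il1rn by 1.32, Il6 by 1.14 and Cxcl2 by 0.94. Of 9 neutrophil genes 6 rose and 7 when adjusted over the list alone (median 0.87, camera adjusted p = 0.000298, and adjusted p = 0.236 with an estimated correlation). Retnlg rose by 2.11 and Cxcr2 by 1.83. Among 13 acute phase and complement genes 4 rose and 1 fell, with Serpina3n up by 4.92 and the fibrinogen chains Fgg, Fgb and Fga up by 4.04, 3.61 and 2.52 (camera adjusted p = 0.0649 for the list). Among 10 macrophage genes 2 rose (Cd14 by 2.52, Cd68 by 1.93) and 2 fell (Cd74 by 1.72, Csf1r by 1.03), and the list was not called (median -0.02, mean 0.10, camera adjusted p = 0.956). Of 9 p53 targets 6 rose, also when adjusted over the list alone (median 0.84, camera adjusted p = 0.00215, and adjusted p = 0.18 with an estimated correlation). Trp53inp1 rose by 1.24 and Mdm2 by 0.88. Of 10 fibrosis and matrix genes 5 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone (median 0.47, camera adjusted p = 0.0201, and adjusted p = 0.318 with an estimated correlation). Lox rose by 1.97, Tnc by 1.56 and Ccn2 by 1.37, whereas Fn1 fell by 0.67. The other larger rise by rank was Sprr2f, an epithelial envelope protein, by 4.32.

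Genes of tubule transport fell in every segment tested. Of 16 proximal tubule genes 13 fell and 14 when adjusted over the list alone (median -1.27, camera adjusted p = 4.06e-08, and adjusted p = 0.236 with an estimated correlation). The lactate carrier Slc5a12 fell by 2.28, and the dicarboxylate carrier Slc13a3 and the water channel Aqp1 were lower (-2.23 and -1.93). Of 6 thick ascending limb genes 5 fell and 6 when adjusted over the list alone (median -2.02, camera adjusted p = 0.000247, and adjusted p = 0.236 with an estimated correlation). Egf fell by 3.55, the salt carrier Slc12a1 by 2.52, and the potassium channel Kcnj1 was lower (-2.17). Of 5 distal convoluted tubule genes 4 fell and 5 when adjusted over the list alone (median -1.73, camera adjusted p = 0.000216, and adjusted p = 0.115 with an estimated correlation), with Pvalb down (-2.81). Of 11 collecting duct genes 8 fell and 9 when adjusted over the list alone (median -1.05, camera adjusted p = 2.79e-07, and adjusted p = 0.115 with an estimated correlation), with the anion exchanger Slc4a1 down (-2.45). In AKI 4 the proximal tubule, thick ascending limb and distal convoluted tubule lists lay 1.02, 1.10 and 1.20 above the other AKI arrays.

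Many genes of mitochondrial energy use fell. Of 21 oxidative phosphorylation genes 17 fell and 18 when adjusted over the list alone (median -0.56, camera adjusted p = 1.87e-08, and adjusted p = 0.236 with an estimated correlation). Ppargc1a, a regulator of mitochondrial gene expression, fell by 1.33 and the complex I subunit Ndufs3 by 0.76. Of 19 citric acid cycle genes 11 fell, also when adjusted over the list alone (median -0.36, camera adjusted p = 3.85e-05, and adjusted p = 0.319 with an estimated correlation). The succinate dehydrogenase subunits Sdhb, Sdhc and Sdha fell by 0.77, 0.76 and 0.66. All 6 gluconeogenesis genes fell (median -1.31, camera adjusted p = 0.000591, and adjusted p = 0.236 with an estimated correlation), G6pc by 2.09, Slc37a4 by 1.68, Slc2a2 by 1.57 and Pck1 by 1.04. Of 21 fatty acid oxidation genes 7 fell and 2 rose, and 8 fell and 2 rose when adjusted over the list alone (median -0.30, camera adjusted p = 0.0498, and adjusted p = 0.65 with an estimated correlation). Acaa2 fell by 1.06 and Ppara by 0.93, whereas Acot2 rose by 1.22. Of 19 glycolysis genes 5 fell and 3 rose (camera adjusted p = 0.52), with Pfkm down (-1.52), Aldoc down (-1.14), Pdk1 down (-1.07) and Pfkl down (-0.99). Of 26 HIF targets 9 rose and 1 fell (median 0.31, camera adjusted p = 0.0923), with the lipid droplet protein Plin2 up by 2.78, Angptl4 by 2.12 and Ddit4 by 1.96.

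Sex-linked and sex-biased genes were among the largest changes. Slc7a12, a transporter of the female-biased list, fell by 6.43, and all 3 measured genes of that list fell (median -3.31, camera adjusted p = 0.000186, and adjusted p = 0.0615 with an estimated correlation). Uty rose by 3.06, Eif2s3y by 3.00 and Kdm5d by 0.95. Of 7 male-biased genes 3 rose over all genes and 7 when adjusted over the list alone (median 2.61, camera adjusted p = 0.00698, and adjusted p = 0.429 with an estimated correlation), with Acsm3 among them. The call ended without control 2 (adjusted p = 0.0553). The 4 sex chromosome genes (median 1.97, mean 0.17) were not called by camera (adjusted p = 0.48). By rank, Serpina6 fell by 5.21, Akr1c18 by 4.42, Igf2 by 4.22, Hao2 by 3.77, Hdc by 3.63 and Rdh16f2 by 3.55.

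In all, limma called 2632 genes higher and 2968 lower (7613 at an unadjusted p under 0.05), 493 and 601 of them by at least 2-fold. The balance turned after centring, with 3032 higher and 2723 lower. It was 2807 and 2974 after quantile scaling and 2663 and 3131 after cyclic loess. Of all genes 27.3% separated the 5 AKI from the 3 control arrays, against 3.57% by chance. No list call of camera held with an estimated correlation (0 of 20 called lists, smallest adjusted p = 0.0615). With the sex-linked level as a covariate limma called 0 genes (712 at an unadjusted p under 0.05). The median standard error then rose from 0.101 to 0.433. The difference was then 3.54 (SE 2.79) for Havcr1, 5.37 (SE 2.36) for Krt20, 4.54 (SE 1.04) for Lcn2, 6.39 (SE 1.83) for Serpina3n, 5.24 (SE 1.40) for Hmox1 and 3.34 (SE 2.88) for Slc7a11. The errors grew and the estimates moved too, that of Havcr1 from 5.75. Injury and sex-linked signal can hardly be separated in this design. Of 131 named calls 111 held with any array left out. The largest losses were 18, 10 and 9 calls without controls 1, 2 and 3, among them Fn1 and Trp53inp1. The call of fatty acid oxidation ended without any 1 of the controls, VHL-KO 2 or 3, AKI 1, 2, 3 or 5, or VHL-KO/AKI 1 or 5, and that of fibrosis and matrix without AKI 1.

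**Figure D3:**
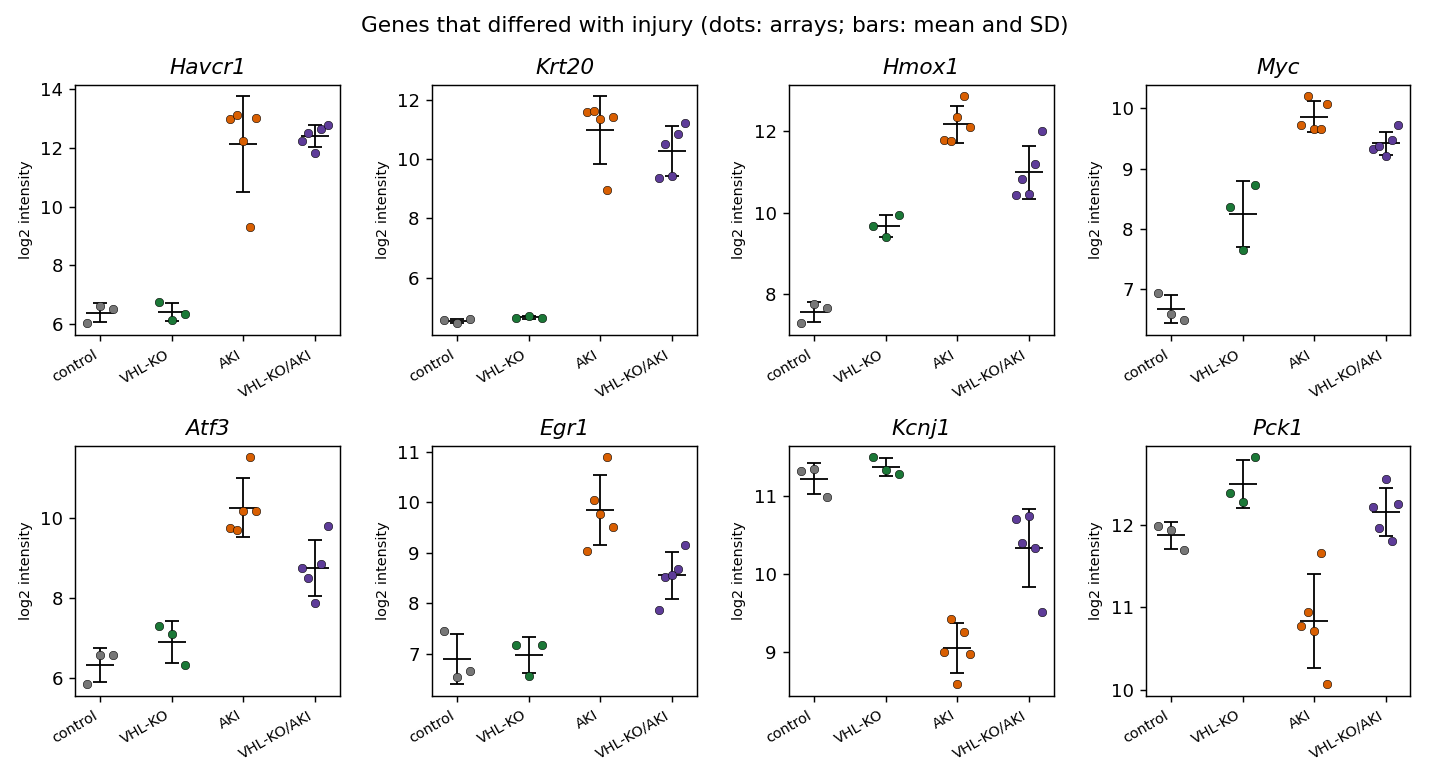
Log2 intensity of 8 genes that differed with injury, by group, with 1 dot per array and bars for the mean and SD (n = 3, 3, 5 and 5). Havcr1 is at 12.14 ± 1.63 in AKI, with AKI 4 at 9.3, and at 12.40 ± 0.38 in VHL-KO/AKI. Kcnj1 lies between 8.59 and 9.43 in AKI and between 9.51 and 10.74 in VHL-KO/AKI.

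VHL-KO/AKI against AKI asked what the knockout changes in the injured kidney, between groups with the same sex-linked signal. Genes of glycolysis and HIF targets rose. Pfkl rose from 7.30 ± 0.39 to 9.57 ± 0.13 (SD, n = 5 and 5), a log2 change of 2.27 (SE 0.17, adjusted p = 7.38e-06). Pdk1 rose by 2.07 (SE 0.163, adjusted p = 9.01e-06) and Egln3 by 2.67 (SE 0.273, adjusted p = 0.0001). Car9, a carbonic anhydrase, rose from 6.16 ± 0.42 to 8.86 ± 0.62 (log2 change 2.70, adjusted p = 0.000216). The apolipoproteins Apoc3 and Apoa4 rose by 2.78 and 2.55, the cytokine receptor Il17rb by 2.57 and Defb19 by 2.38. Vmn1r32, chosen after its values were seen, rose by 5.02 (SE 0.216, adjusted p = 8.83e-09). Each of these genes was higher in all 5 VHL-KO/AKI arrays than in all 5 AKI arrays.

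Of 26 HIF targets 12 rose and 0 fell, and 12 rose and 2 fell when adjusted over the list alone (median 0.32, camera adjusted p = 3.43e-07, and adjusted p = 0.231 with an estimated correlation). Bnip3 rose by 1.78 and the transferrin receptor Tfrc by 1.02. Of 19 glycolysis and lactate genes 11 rose, 0 fell and 8 did not pass, and 12 rose when adjusted over the list alone (median 0.73, camera adjusted p = 8.95e-13, and adjusted p = 0.133 with an estimated correlation). Slc16a3 rose by 2.00 and Pfkp by 1.42. Of 21 fatty acid oxidation genes 2 rose and 9 when adjusted over the list alone (median 0.38, camera adjusted p = 2.67e-07, and adjusted p = 0.284 with an estimated correlation). The 2 were the regulator Ppara, up by 0.92, and Hadha, up by 0.35. Of 6 gluconeogenesis genes 2 rose and 4 when adjusted over the list alone, Pck1 by 1.32 and Slc37a4 by 1.31 (median 0.75, camera adjusted p = 0.00015, and adjusted p = 0.251 with an estimated correlation). The citric acid cycle (0 of 19, camera adjusted p = 0.0984) and oxidative phosphorylation (0 of 21, camera adjusted p = 0.257) were not called.

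Some injury and stress genes fell with the knockout. Immediate early genes fell in 4 of 12 cases and in 10 when adjusted over the list alone (median -0.93, camera adjusted p = 3.45e-08, and adjusted p = 0.251 with an estimated correlation). Atf3 fell from 10.26 ± 0.74 to 8.76 ± 0.70 (log2 change -1.50, SE 0.369, adjusted p = 0.0378), Egr1 by 1.30, Klf6 by 0.94 and Jun by 0.92. Of 17 tubular injury markers 4 fell and 6 when adjusted over the list alone (median -0.50, camera adjusted p = 0.000178, and adjusted p = 0.345 with an estimated correlation). The receptor Plaur fell by 1.22, the transcription factor Fosl1 by 1.08, and the keratins Krt18 and Krt8 by 0.90 and 0.51. Havcr1 was not among them, at 12.14 ± 1.63 and 12.40 ± 0.38, with AKI 4 at 9.3 and the other AKI arrays between 12.23 and 13.13. Of 16 cytokines and chemokines 3 fell and 5 when adjusted over the list alone (median -0.22, camera adjusted p = 4.92e-05, and adjusted p = 0.133 with an estimated correlation), Il6 by 1.00, Socs3 by 0.98 and Csf1 by 0.46. Of 9 neutrophil genes 2 fell and 5 when adjusted over the list alone (median -0.55, camera adjusted p = 1.33e-05, and adjusted p = 0.251 with an estimated correlation), with S100a9 down (-1.07) and S100a8 down (-0.55). In AKI 4 the immediate early and neutrophil lists lay 1.06 and 0.565 above the other AKI arrays, and the tubular injury list differed from them by -0.637.

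Further lists were lower with fewer members past the test. Of 18 haem and oxidative stress genes 2 fell and 3 when adjusted over the list alone, Hmox1 by 1.18 and Txnrd1 by 0.90 (camera adjusted p = 0.00763, and adjusted p = 0.345 with an estimated correlation). Of 12 heat shock and endoplasmic reticulum stress genes Atf4 fell by 0.63 (1 of 12, and 3 when adjusted over the list alone; camera adjusted p = 0.0115, and adjusted p = 0.287 with an estimated correlation). Of 13 proliferation genes Top2a fell by 0.60 (1 of 13, and 2 when adjusted over the list alone; camera adjusted p = 0.00459, and adjusted p = 0.251 with an estimated correlation). Of 9 p53 targets Mdm2 fell by 0.55 (1 of 9; camera adjusted p = 0.0398, and adjusted p = 0.344 with an estimated correlation). The call ended after centring and without AKI 3, AKI 5, VHL-KO/AKI 2 or VHL-KO/AKI 3. Among called genes whose groups did not overlap in any array, the largest falls were those of Gprc5a (-1.88), the oxidative stress gene Osgin1 (-1.53), the kinase Plk3 (-1.31), the phosphatase Dusp5 (-1.25), Sfn (-1.24), the prostaglandin synthase Ptgs2 (-1.22), the growth factor Hbegf (-1.21) and the matrix protein Ccn1 (-1.20).

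Some genes of the thick ascending limb and collecting duct rose with the knockout. Of 6 thick ascending limb genes Cldn10 rose by 1.30 and Kcnj1 by 1.28 (2 of 6, also when adjusted over the list alone; median 1.20, camera adjusted p = 0.000201, and adjusted p = 0.251 with an estimated correlation). Of 11 collecting duct genes 3 rose and 5 when adjusted over the list alone, the sodium channel subunits Scnn1g by 0.82 and Scnn1b by 0.40 and Atp6v0d2 by 0.39 (median 0.39, camera adjusted p = 6.8e-05, and adjusted p = 0.251 with an estimated correlation). The proximal tubule list was not called (0 of 16, median 0.09, camera adjusted p = 0.299), nor was the distal convoluted tubule list (0 of 5, camera adjusted p = 0.257). Bnip3l rose by 0.71 and the adaptor Sqstm1 fell by 0.38. The matrix proteoglycan Dcn rose by 0.69, whereas the smooth muscle genes Tagln and Acta2 fell by 0.93 and 0.57. Cyp4a14, of the female-biased list, rose by 2.12 (1 of 3, camera adjusted p = 0.0507).

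In all, limma called 495 genes higher and 279 lower (3734 at an unadjusted p under 0.05), 63 and 28 of them by at least 2-fold. After centring 359 were higher and 400 lower, after quantile scaling 395 and 417, and after cyclic loess 433 and 340. Of the called genes 439 separated all arrays of both groups. Of all genes 3.78% did so, against 0.794% by chance for 5 against 5. No list call held with an estimated correlation (0 of 14, smallest adjusted p = 0.133). The count was 2384 without AKI 4, 292 without AKI 3, 340 without AKI 5, 229, 291, 258 and 485 without VHL-KO/AKI 1 to 4, and 1591 without VHL-KO/AKI 5. Of 58 named calls 26 held with any array left out. Vhl, Pfkl, Pdk1, Egln3, Car9, Slc16a3, Pck1, Jun, Il6, Kcnj1 and S100a9 were among these, and Atf3, Egr1, Hmox1, Plaur, Fosl1, Krt8, Krt18, Socs3 and Cldn10 were not. The losses were 26 and 27 calls without AKI 3 and AKI 5, and 30, 27, 29 and 12 without VHL-KO/AKI 1 to 4. They were 12 without AKI 1, 6 without AKI 2 and 4 to 9 without any 1 of the uninjured arrays. Per3 was lost under all 3 scalings, and Hadha, Slc37a4, S100a8, Sqstm1 and Arntl under at least 1.

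VHL-KO/AKI against VHL-KO asked what injury changes in knockout kidneys, again between arrays of opposite sex-linked signal. Havcr1 rose from 6.41 ± 0.30 (SD, n = 3) to 12.40 ± 0.38 (n = 5), a log2 change of 5.99 (SE 0.646, adjusted p = 5.92e-05). Krt20 rose by 5.60, Lcn2 by 4.24 and Serpina3n by 4.72. Of 17 tubular injury markers 12 rose and 13 when adjusted over the list alone (median 1.17, camera adjusted p = 1.81e-12, and adjusted p = 0.108 with an estimated correlation). Xist fell by 7.02 in the same arrays.

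Stress genes rose in this comparison too. Of 18 haem and oxidative stress genes 13 rose and 1 fell, and 15 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.36e-11, and adjusted p = 0.0637 with an estimated correlation), with Slc7a11 up by 3.41, Srxn1 by 2.34 and Nqo1 by 2.14. Of 12 heat shock and endoplasmic reticulum stress genes 7 rose and 9 when adjusted over the list alone, Hspb1 by 2.74 and Hspa1a by 1.93 (camera adjusted p = 3.04e-07, and adjusted p = 0.0637 with an estimated correlation). Of 12 immediate early genes 4 rose, also when adjusted over the list alone, Atf3 by 1.85 and Egr1 by 1.58 (camera adjusted p = 0.000206, and adjusted p = 0.294 with an estimated correlation). Of 13 acute phase genes 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.000673, and adjusted p = 0.142 with an estimated correlation), with Fgg up by 3.96. Of 16 cytokines 2 rose, Socs3 by 1.02 and Cxcl1 by 0.70 (camera adjusted p = 0.0538 for the list). Of 9 p53 targets Perp rose by 0.48 (1 of 9, and 2 when adjusted over the list alone; camera adjusted p = 0.0342, and adjusted p = 0.294 with an estimated correlation). The call ended after centring and without VHL-KO 2, VHL-KO/AKI 4 or VHL-KO/AKI 5.

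Some genes of tubule transport, oxidative phosphorylation, the citric acid cycle and endothelium fell. Of 5 distal convoluted tubule genes all 5 fell, also when adjusted over the list alone, Pvalb by 2.70 (camera adjusted p = 1.26e-05, and adjusted p = 0.0806 with an estimated correlation). Of 16 proximal tubule genes 7 fell and 11 when adjusted over the list alone, Slc5a12 by 1.76 (camera adjusted p = 0.000591, and adjusted p = 0.442 with an estimated correlation). Of 11 collecting duct genes 5 fell and 8 when adjusted over the list alone, Slc4a1 by 2.28 (camera adjusted p = 0.000501, and adjusted p = 0.242 with an estimated correlation). Of 6 thick ascending limb genes Kcnj1 fell by 1.03 (1 of 6, and 2 when adjusted over the list alone; camera adjusted p = 0.0428, and adjusted p = 0.454 with an estimated correlation). The call ended without VHL-KO 1, VHL-KO 2 or VHL-KO/AKI 5. Of 21 oxidative phosphorylation genes 9 fell and 19 when adjusted over the list alone, Ppargc1a by 0.98 (camera adjusted p = 3.71e-07, and adjusted p = 0.294 with an estimated correlation). Of 19 citric acid cycle genes 4 fell and 5 when adjusted over the list alone, Sdhc by 0.61 (camera adjusted p = 0.000501, and adjusted p = 0.384 with an estimated correlation). Of 21 fatty acid oxidation genes Cpt2 rose by 0.57 and Acaa2 fell by 0.94, and the list was not called (median -0.08, camera adjusted p = 0.989). Both gene calls ended without VHL-KO 1, VHL-KO 2, VHL-KO/AKI 4 or VHL-KO/AKI 5, Cpt2 also without VHL-KO/AKI 3 (adjusted p up to 0.164), and Acaa2 also without VHL-KO 3, VHL-KO/AKI 1 or VHL-KO/AKI 2 (up to 0.127). The 6 gluconeogenesis genes did not pass (0 of 6, median -0.59, camera adjusted p = 0.052). Of 8 endothelial genes 4 fell, also when adjusted over the list alone, the receptor Kdr by 0.98 and Tie1 by 0.82 (camera adjusted p = 0.000441, and adjusted p = 0.0943 with an estimated correlation).

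Among cells of blood and division, Alas2 fell by 1.99 (1 of 2 erythrocyte genes, camera adjusted p = 0.039, and adjusted p = 0.193 with an estimated correlation). The call ended without VHL-KO 1, VHL-KO 3, AKI 4 or VHL-KO/AKI 3. Of 13 proliferation genes 5 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone, Ccna2 by 1.36 and Mki67 by 1.15 (median -0.30, camera adjusted p = 0.00155, and adjusted p = 0.186 with an estimated correlation). Of 26 HIF targets 3 rose, Plin2 by 1.95, Car9 by 1.87 and Tfrc by 1.04, and 4 fell, P4ha1 by 0.75 among them (camera adjusted p = 0.393). Of 19 glycolysis genes Slc16a3 rose by 0.81, whereas Aldoc and Pfkl fell by 1.29 and 0.73 (camera adjusted p = 0.458). Sex-biased genes were prominent again. All 7 male-biased genes rose (median 4.15, camera adjusted p = 5.26e-08, and adjusted p = 0.128 with an estimated correlation), Acsm3 by 6.42, Cyp2j13 by 5.04 and Slc7a13 by 4.91. Of 3 female-biased genes 2 fell, Slc7a12 and Abcc3 (-5.51 and -3.35; camera adjusted p = 0.000485, and adjusted p = 0.0637 with an estimated correlation). By rank, Timd2 rose by 5.50 and Pzp by 4.51, and Serpina6 fell by 6.39, Igf2 by 4.22, Hao2 by 3.55, Hdc by 3.46, and Wfdc16 was lower (-2.93). Pzp was at 9.42 in uninjured control 3, the array with Y-linked signal, and at 4.96 and 4.84 in controls 1 and 2. Timd2 was at 8.84 in control 3 and at 6.27 and 5.94 in controls 1 and 2.

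In all, limma called 929 genes higher and 1776 lower (5442 at an unadjusted p under 0.05), 217 and 230 of them by at least 2-fold. The balance of called genes depended on scaling, with 1700 higher and 1151 lower after centring (2080 of the 2705 calls kept), 1193 and 1339 after quantile scaling and 1264 and 1352 after cyclic loess. Of all genes 24.3% separated the groups, against 3.57% by chance. No list call held with an estimated correlation (0 of 23, smallest adjusted p = 0.0637). With the sex-linked level as a covariate limma called 0 genes (359 at an unadjusted p under 0.05), with the median standard error up from 0.101 to 0.509. The difference was then 3.37 (SE 3.28) for Havcr1, 4.34 (SE 2.77) for Krt20, 3.55 (SE 1.22) for Lcn2, 6.45 (SE 2.15) for Serpina3n, 2.07 (SE 1.65) for Hmox1 and 2.38 (SE 3.38) for Slc7a11. The count was 1754 without VHL-KO 1 and 1683 without VHL-KO 3. Of 101 named calls 68 held with any array left out, with 20, 21 and 24 lost without VHL-KO 1, 2 and 3 and 11, 14 and 12 without VHL-KO/AKI 2, 4 and 5.

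**Figure D4:**
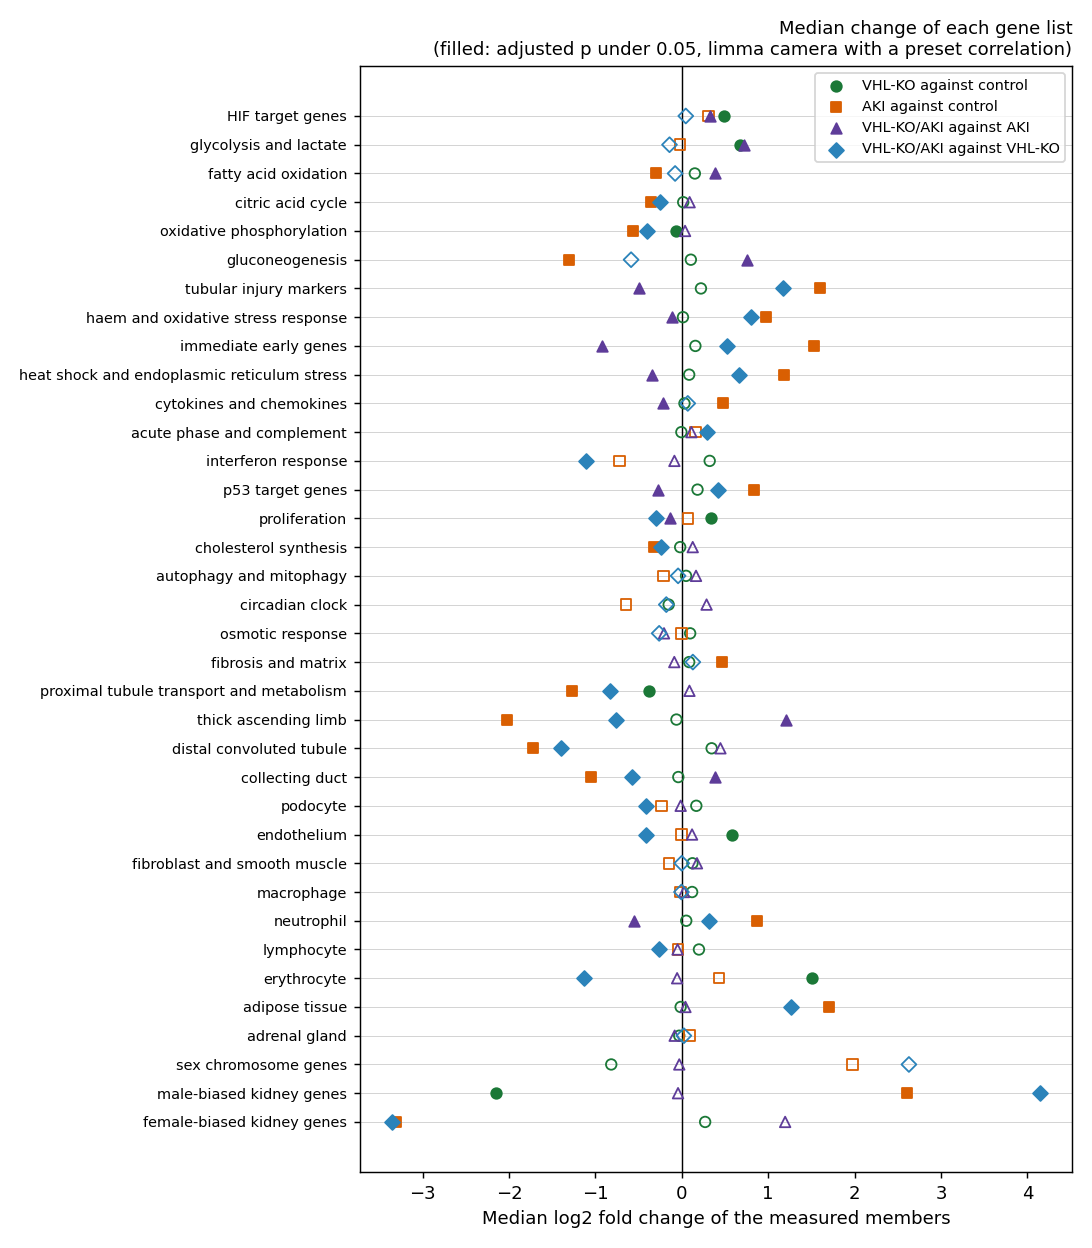
Median log2 fold change of the measured members of each of 36 gene lists, with 1 marker shape and colour per comparison and filled markers where camera at the preset correlation gave an adjusted p under 0.05. Glycolysis lies at 0.68 and 0.73 in the knockout comparisons, and tubular injury markers at 1.60 and 1.17 in the injury comparisons.

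The interaction asked whether the knockout difference differed between injured and uninjured arrays. Because these arrays also differ in sex-linked signal, the interaction cannot tell a change with injury from a change with sex. It was called for Hmox1 (-3.29, SE 0.453, adjusted p = 0.0466) and Myc (-2.02, SE 0.289, adjusted p = 0.0466). Hmox1 rose with the knockout in uninjured kidneys, from 7.56 ± 0.25 to 9.67 ± 0.27 (SD, n = 3 and 3), and fell with it in injured kidneys, from 12.17 ± 0.45 to 10.99 ± 0.66 (n = 5 and 5). Myc was at 6.67 ± 0.24 in controls, 8.25 ± 0.54 in VHL-KO, 9.86 ± 0.26 in AKI and 9.42 ± 0.19 in VHL-KO/AKI. Adm (-1.63), Ccn2 (-1.35) and Jun (-1.36) had the next values (adjusted p = 0.0791 each), followed by Alas2 (-1.66, adjusted p = 0.0939) and Car9 (2.35, adjusted p = 0.0957). As lists, immediate early genes (median -1.16, camera adjusted p = 4.83e-07), proliferation (median -0.47, camera adjusted p = 4.14e-08) and tubular injury markers (median -0.78, camera adjusted p = 0.000161) lay lower. With an estimated correlation the adjusted p were 0.345, 0.0793 and 0.449. Thick ascending limb (median 1.21, camera adjusted p = 0.000721) and collecting duct (median 0.50, camera adjusted p = 7.2e-05) lay higher. With an estimated correlation the adjusted p were 0.444 and 0.345. Glycolysis (median -0.00, camera adjusted p = 0.824) and HIF targets (median -0.27, camera adjusted p = 0.0749) were not called.

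Limma called 0 genes higher and 2 lower in the interaction, with 2387 at an unadjusted p under 0.05. It called 0 without any 1 of the 3 controls, AKI 1, 3 or 5, or VHL-KO/AKI 1, 2 or 4, and 1 without VHL-KO 1, VHL-KO 3 or VHL-KO/AKI 3, which was neither Hmox1 nor Myc in any of the 3. It called 9 without VHL-KO 2, 21 without AKI 2, 620 without AKI 4 and 206 without VHL-KO/AKI 5. Hmox1 and Myc each held in 4 of 16 such fits, with an adjusted p up to 0.183 (without control 3). The Myc call ended after quantile scaling (adjusted p = 0.0525).

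The knockout differences with and without injury were compared across genes from arrays that the 2 comparisons do not share. The injured and uninjured arrays also differ in sex-linked signal. Both comparisons called 45 genes higher, against 2.36 expected of independent lists, and 3 lower (Abcc2, Dnase1 and Gng12), against 0.14. A single gene (1) went opposite ways. The shared rises included Adm, Bnip3, Bnip3l, Egln1, Egln3, Ldha, P4ha1, P4ha2, Pdk1, Pfkl, Pfkp, Pgam1, Pgk1 and Slc16a3. Over all 19938 genes, which are not independent replicates, Pearson's r was 0.132. It ranged from 0.055 without AKI 4 to 0.184 without VHL-KO/AKI 3, and VHL-KO 3 and VHL-KO/AKI 4 and 5 took it to 0.091, 0.094 and 0.084. The injury differences with and without the knockout had r = 0.82, with 710 shared rises (122.6 expected), 1284 shared falls (264.4 expected) and 6 genes in opposite directions. Both injury differences also compare arrays of opposite sex-linked signal.

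Whether the knockout difference in injured kidneys ran against the injury difference was tested with the AKI arrays divided, so that no AKI array entered both sides. Over the genes called between control and some of the AKI arrays (3077 to 6278 genes), the difference between VHL-KO/AKI and the other AKI arrays had a median slope of -0.306 on the injury difference. Across the 10 divisions the slope ranged from -0.369 to -0.07 and r from -0.765 to -0.177, with a median of 84.0% of genes in opposite directions. With AKI 4 among the arrays compared with VHL-KO/AKI the slope lay between -0.133 and -0.07, and otherwise between -0.369 and -0.299. Without AKI 5 the median slope was -0.184. Genes are not independent replicates here, so no p is given. The injury difference used here also holds the opposite sex-linked signal.

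**Figure D5:**
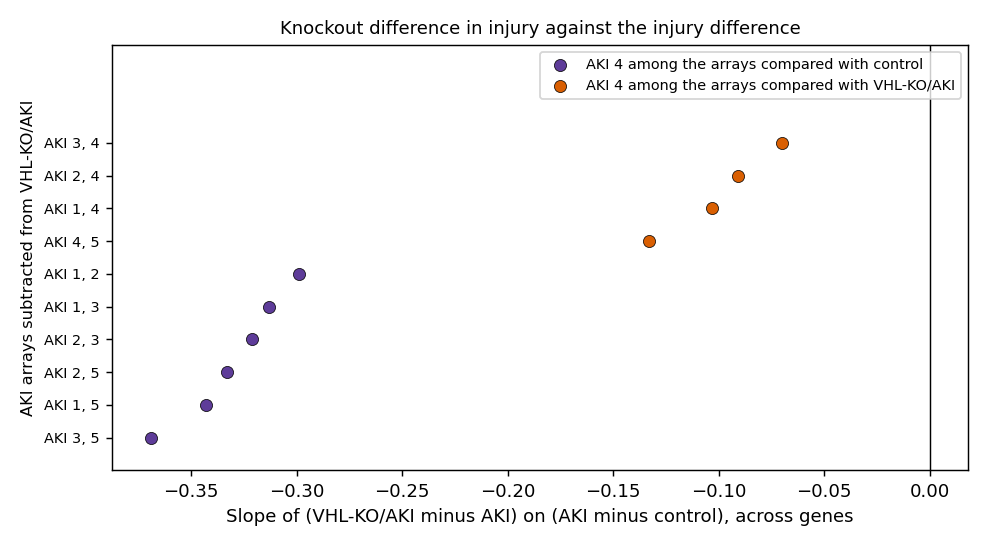
Slope, across genes, of the VHL-KO/AKI minus AKI difference on the AKI minus control difference, with 1 dot for each of 10 divisions of the AKI arrays. All 10 slopes lie below 0, between -0.369 and -0.07, and the 4 with AKI 4 among the arrays compared with VHL-KO/AKI lie nearest to 0.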

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

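The splits of the arrays were planned, and the tests of sex, of AKI 4 and of the lower injury genes in VHL-KO/AKI were chosen only after the results were seen.

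The first pattern is the sex-linked signal. The lowest Xist level of the uninjured arrays lay 5.15 above the highest of the injured arrays, and the male-biased and female-biased lists moved as mice of different sex in the 2 sets of groups would give. For Xist and the Y-linked genes, injury without a difference of sex is argued against. The Y-linked mean was 4.81 to 5.01 in controls 1 and 2 and VHL-KO, and 7.77 to 8.26 in the injured arrays. Control 3, which was uninjured, had 7.43. For the sex-biased genes, a difference of sex is a candidate explanation beside injury. For all other genes called between VHL-KO/AKI and VHL-KO, control 3 with its Y-linked signal was compared with controls 1 and 2, and its difference had a slope of 0.179 on the injury difference (r = 0.496 over 2692 genes, which are not independent replicates). The slope over the sex lists was 0.713. With 1 such array, sex and injury cannot be told apart for these genes, and the tubular injury list, for example, differed by -0.082 in control 3 and by 1.17 with injury.

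The next pattern is AKI 4, which stood far from the other 4 AKI arrays. The gap to its nearest neighbour, as a share of the group's range, was 0.936 for the correlation with its own group, 0.83 and 0.752 for the first and second components, and 0.736 for HIF targets, 0.789 for glycolysis, 0.907 for the citric acid cycle, 0.876 for oxidative phosphorylation, 0.772 for haem and oxidative stress (lowest), 0.851 for cholesterol synthesis, 0.757 for the circadian clock, 0.763 for the thick ascending limb and 0.801 for the distal convoluted tubule. Such a gap arises by chance in about 1 in 20 groups, and 84 were examined, with 13 past the limit against 4.2 by chance. RNA mixed in from uninjured kidneys with Xist signal is argued against by Xist, which allows a share of 0.59%. Havcr1 would need 92.7%, Krt20 83.4%, Lcn2 45.3% and Serpina3n 2.19%. Xist cannot decide on RNA of an uninjured male kidney, which would add no Xist, and the labels say that both sexes were used. The mean of the immediate early list, relative to controls, was 2.686 in AKI 4. It was 1.222 to 2.075 in the other AKI arrays and 0.037 in control 3, with its Y-linked signal. Uninjured RNA would lower these genes, so for them its admixture is argued against. The tubular injury list and the other lists are not decided by this. A VHL-KO/AKI kidney under a wrong label is argued against by Egln3, at -1.20 relative to the lowest VHL-KO/AKI array. Weaker or earlier injury in this mouse may remain. Relative to the other AKI arrays, its injury list lay at -0.637, but its immediate early and neutrophil lists lay at 1.06 and 0.565. Weaker or earlier injury cannot be told apart from other causes without a measure of time or severity.

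The remaining pattern is the lower level of injury and stress genes in VHL-KO/AKI than in AKI. AKI 4 alone is argued against by the lists without it, with medians of -0.65 for tubular injury markers, -0.66 for immediate early genes and -0.31 for heat shock and endoplasmic reticulum stress (camera adjusted p = 6.44e-07, 9.73e-06 and 0.0138), whereas the 942 lower genes of all kinds without it (279 with it) do not bear on these genes alone. These p are for the preset correlation. With all arrays, no list call of this comparison held under camera with an estimated correlation (smallest adjusted p = 0.133), which was not run without AKI 4. Mice of different sex in these 2 groups are argued against by Xist, which differed by -0.10. Doxycycline itself cannot be told apart from the knockout, because no mice received doxycycline without it (injury list median -0.50). An effect of the deletion therefore stays open as a hypothesis and was not tested apart from the drug.

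The Y-linked level of AKI 2 lay below the other AKI arrays by 0.772 of the group's range.

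By the interaction test of limma, the knockout difference differed between injured and uninjured arrays for Hmox1 (-3.29) and Myc (-2.02), each with adjusted p = 0.0466. Injury and sex-linked signal cannot be told apart in this test. Each call was lost without any 1 of the 3 controls, VHL-KO 1 and 3, AKI 1, 3 and 5, and VHL-KO/AKI 1 to 4, which is 12 of 16 fits (adjusted p up to 0.183). For lists, camera at the preset correlation gave medians of 0.21 for fatty acid oxidation, 0.11 for oxidative phosphorylation, 0.83 for gluconeogenesis, 0.52 for the proximal tubule, 1.21 for the thick ascending limb, 0.50 for the collecting duct and 1.84 for male-biased kidney genes. The medians were -0.78 for tubular injury markers, -1.16 for immediate early genes, -0.50 for heat shock and endoplasmic reticulum stress, -0.26 for cytokines and chemokines, -0.47 for proliferation, -0.38 for fibrosis and matrix, -0.41 for endothelium, -0.71 for neutrophils and -1.56 for erythrocytes. With an estimated correlation 0 of the 16 passed (smallest adjusted p = 0.0793). Without single arrays 11 of the 16 held. Male-biased genes did not pass without control 3 (adjusted p = 0.209), heat shock without control 1 (0.0612), fatty acid oxidation without VHL-KO 2, AKI 1 or VHL-KO/AKI 3 (up to 0.111), and oxidative phosphorylation without these or control 1 (up to 0.123). Fibrosis and matrix did not pass without any 1 of controls 1 and 3, VHL-KO 1 and 2, AKI 1, 2 and 5, and VHL-KO/AKI 1, 3 and 4 (up to 0.171).

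Among the array features that were not tested, 10 changed the same way in both knockout comparisons. Of these, 4 are further features of tested genes (Pgk1 with 2, Bnip3l and Pkm). The largest pair, which match 8 and 9 genes of the vomeronasal receptor family, rose by 4.58 and 3.49 without injury and by 4.63 and 3.36 with it.

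Other splits of the arrays were counted for each comparison. For AKI against control, 1 of 56 splits (the real one) gave as many as 5600 genes, and the highest other gave 2560. For VHL-KO/AKI against VHL-KO, 1 of 56 gave as many as 2705, and the highest other gave 1. For both, 1 of 56 is the smallest share that 56 splits can give. It is under 0.05, which argues against chance without excluding it, and the splits do not bear on the difference of sex. For VHL-KO/AKI against AKI, 3 of 100 splits drawn from 126 gave as many as 774, the real one among them. The share is under 0.05, but other splits gave 2671 and 1209 genes, so chance is not taken as excluded. The split with 2671 set AKI 1, 2, 3 and 5 with VHL-KO/AKI 5 against AKI 4 with VHL-KO/AKI 1 to 4, which points to a structure of the samples. For the interaction, 2 of 100 splits drawn from 2520 gave as many as 2 genes, and the highest other gave 4. The share is under 0.05, but with 2 genes against 4 in another split chance is not taken as excluded. For VHL-KO against control, the 10 splits are too few for a share under 0.05, with 105 genes in the real split (1 of 10) and 3 in the highest other.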

How the results depend on the processing

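Leaving out control 3 and AKI 4 together was chosen after the results were seen. Over all alternatives, 13297 values of named genes kept direction and side of the threshold, 1100 fell short of it, 162 passed it anew and 39 changed sign. For gene lists, judged by the direction that the list test gives, the counts were 3799, 202, 119 and 15 with the opposite direction. Vmn1r32 and Vmn1r38, chosen after their values were seen, are not in these counts, and their values under the alternatives were not tabulated. The cause was not tested in any case below unless it is given.

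Leaving out single arrays gave 34 to 235 genes for VHL-KO against control (105 with all arrays), 4248 to 6811 for AKI against control (5600), 229 to 2384 for VHL-KO/AKI against AKI (774), 1683 to 3910 for VHL-KO/AKI against VHL-KO (2705) and 0 to 620 for the interaction (2). Agreement of the knockout differences ranged from 0.055 to 0.184 (0.132) and the slope against injury from -0.375 to -0.184 (-0.306). With control 3 and AKI 4 both left out, VHL-KO/AKI against AKI had 2196 genes, the interaction 22, and the agreement was 0.077.

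For VHL-KO against control, centring gave 60 genes, cyclic loess 66, array weights 319, the replicate block 65, the sex-linked covariate 18 and an adjusted p under 0.01 33. For VHL-KO/AKI against AKI, array weights gave 2868 genes, the compared groups alone 223, a fold of at least 1.5 299 and an adjusted p under 0.01 149. For VHL-KO/AKI against VHL-KO, array weights gave 4328, the fold limit 1211 and the stricter p 1214. For AKI against control the fold limit gave 2790 and the stricter p 3525. The lower counts under the fold limit and the stricter p follow from their construction. For the interaction, all array features gave 5, features with 1 symbol 0, quantile scaling 1, array weights 885, the replicate block 1, the sex-linked covariate 0 (1732 at an unadjusted p under 0.05 by limma) and an adjusted p under 0.01 0.

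With the sex-linked level as a covariate limma called 0 genes in AKI against control (712 at an unadjusted p under 0.05) and 0 in VHL-KO/AKI against VHL-KO (359). The median standard error rose from 0.101 to 0.433 and to 0.509, because the covariate nearly equals the injury groups. Injury genes such as Serpina3n (6.39 and 6.45), Krt20 (5.37 and 4.34) and Lcn2 (4.54 and 3.55) kept their sign under it. Within groups the covariate varies mainly through control 3, so a kept or changed sign decides nothing between injury and sex. Under it these genes changed sign in AKI against control: Pdk1 0.006, Pfkl 0.341, Pck1 0.416, Phlda3 -0.148, Rrm2 -0.118, Slc6a12 0.632, Fn1 0.0704, Nkg7 0.0893, Uty -5.26, Eif2s3y -4.17, Kdm5d -1.73, Acsm3 -9.70, Cyp2j13 -10.68, Cyp7b1 -5.95 and Cyp4a14 0.588. Camera gave the opposite direction for sex chromosome genes (median -3.95), male-biased kidney genes (-9.22) and fatty acid oxidation, whose median kept its sign (-0.0088, from -0.30). In VHL-KO/AKI against VHL-KO they were Acsm3 -8.98, Timd2 -3.22, Cyp2j13 -11.04, Slc7a13 -11.03, Pzp -7.68, Car9 -0.995, Tfrc -0.135, Aldoc 0.0132, Pfkl 0.840, Acaa2 0.305, Sdhb 0.01, Idh3b 0.106, Ndufs3 0.140, Atp5o 0.0876, Blvrb -0.325, Calb1 0.358, Nphs1 0.233, Wt1 0.0751, Pecam1 0.0169, Nkg7 0.0879, Uty -5.46, Eif2s3y -4.82, Kdm5d -1.59 and Slco1a1 -9.49. Camera gave the opposite direction there for glycolysis (median 0.211), fatty acid oxidation (0.437), citric acid cycle (0.01), thick ascending limb (0.446), collecting duct (0.102), podocyte (0.0751), sex chromosome genes (-4.39) and male-biased genes (-8.98). It did so too for the interferon response (-0.0138, from -1.11) and female-biased genes (-0.503, from -3.35), whose medians kept their sign. Under fry the sex chromosome list (medians 1.97 and 2.63, the same values as before) had the opposite direction to camera in the 2 injury comparisons.

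With dim genes left out the counts were 97, 5501, 867, 2700 and 2 in the order of the comparisons, each within 1.5 times the count over all genes. This does not show whether changes in dim genes were missed.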

Other observations

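The tests of the erythroid precursor and platelet lists were written before their values were seen, and the vomeronasal receptor pair was chosen after its values were seen.

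Some genes of fat tissue, the clock and cholesterol synthesis also differed with injury. Of 5 adipose genes 4 rose in AKI against control and 5 when adjusted over the list alone (median 1.70, camera adjusted p = 0.00246, and adjusted p = 0.18 with an estimated correlation), with the lipid droplet gene Cidec up by 3.09 and the hormone Adipoq by 1.70. In VHL-KO/AKI against VHL-KO 3 of 5 rose (median 1.26, camera adjusted p = 0.00069, and adjusted p = 0.123 with an estimated correlation), Cidec by 3.23 and Adipoq by 2.60. Levels also varied within groups. The member Ucp1 ranged from 6.1 to 10.21 in AKI and from 5.57 to 9.25 in VHL-KO/AKI, and Cidec from 8.12 to 9.27 and from 7.91 to 10.07. Ucp1 was at 8.27 in uninjured VHL-KO 3 and at 6.29 and 5.44 in VHL-KO 1 and 2. The share of fat tissue in each sample is not known here. The list was not called in VHL-KO against control (median -0.01, mean 0.20, adjusted p = 0.916) or VHL-KO/AKI against AKI (median 0.04, mean -0.12, adjusted p = 0.823). Of 10 clock genes 5 fell and 2 rose in AKI against control (camera adjusted p = 0.0923), with Dbp down (-2.20) and Arntl up by 1.30, and in VHL-KO/AKI against AKI Per3 rose by 0.60 and Arntl fell by 0.76 (adjusted p = 0.0418 and 0.05, limma). Per3 was lost under all 3 scalings (adjusted p up to 0.0585) and without any 1 of the 3 controls, VHL-KO 1, AKI 1, 3 and 5 and VHL-KO/AKI 1 to 3 (up to 0.122). Arntl was lost after cyclic loess (0.0509) and without any 1 of the 3 controls, VHL-KO 2 and 3, AKI 3 and 5 and VHL-KO/AKI 1 to 4 (up to 0.144). Of 10 cholesterol synthesis genes 4 fell in AKI against control (median -0.33, camera adjusted p = 0.00242, and adjusted p = 0.236 with an estimated correlation), Cyp51 by 1.90. In VHL-KO/AKI against VHL-KO 3 fell (camera adjusted p = 0.0194, and adjusted p = 0.294 with an estimated correlation), and the call ended without VHL-KO/AKI 5 (0.0793).

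Further cell types moved in VHL-KO/AKI against VHL-KO. Of 5 podocyte genes 4 fell, Ptpro by 0.82 and Podxl by 0.50 (median -0.41, camera adjusted p = 0.00375, and adjusted p = 0.108 with an estimated correlation). Of 7 interferon response genes 2 fell and 6 when adjusted over the list alone, Rsad2 by 1.66 (camera adjusted p = 0.00289, and adjusted p = 0.294 with an estimated correlation), and the call ended without VHL-KO 1 (0.0671). Of 8 lymphocyte genes Nkg7 fell by 1.13 (camera adjusted p = 0.00585, and adjusted p = 0.325 with an estimated correlation), and the call ended without VHL-KO 1 (0.137). The neutrophil list was called higher (0 of 9 genes passed, camera adjusted p = 0.0495, and adjusted p = 0.479 with an estimated correlation), and the call ended after centring and without any 1 of the uninjured arrays, AKI 3, AKI 4, VHL-KO/AKI 4 or VHL-KO/AKI 5 (up to 0.12). The adrenal gland list was not called in AKI against control (median 0.09, camera adjusted p = 0.47), nor the osmotic response list (median -0.00, mean 0.12, adjusted p = 0.779) or the fibroblast and smooth muscle list (median -0.15, mean 0.16, adjusted p = 0.651). The autophagy list was not called there either (adjusted p = 0.638).

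Alas2 and Ppbp rose in VHL-KO against control, and more erythroid precursor or platelet RNA in these kidneys was tested as a candidate explanation. The erythroid precursor list (14 of 16 measured) had a median of 0.066 (10 of 14 positive), and 10 of the 14 are among the dim genes that the filter on level removes, so the limit of 0.1 set beforehand was wrong for such dim genes and decides nothing. The platelet list (6 of 10 measured) had a median of 0.162, between the limits set. In neither list did a member pass (0 and 0), so both explanations stay open.

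Vmn1r32, chosen after its values were seen, lay between 4.90 and 5.92 in the control and AKI arrays, between 10.54 and 11.62 in VHL-KO and between 9.98 and 10.58 in VHL-KO/AKI. Vmn1r38, of the same receptor family, lay between 4.48 and 4.91 in the control and AKI arrays and between 4.81 and 5.43 in the knockout arrays.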
